A study of Mus musculus with 24 samples.

How the data were processed

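Polyadenylated RNA from mouse liver was sequenced with a stranded library kit in 24 libraries, 3 for each of 8 groups. These combined 4 genotypes, wild type (WT), global Bmal1 knockout (KO), floxed Bmal1 without Cre (F) and liver-specific Bmal1 knockout (LKO), with 2 circadian times, CT2 and CT14. Every library was assigned to its group from its label, and 0 columns were left without a group. The labels do not say whether the 3 replicates of a group came from separate animals. If they did not, the p-values measure only the spread between these samples.

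The authors deposited a table of estimated counts per Ensembl gene, one column per library and not normalized. The authors deposited a second table in TPM, length-corrected transcript levels scaled to the same total in each library. The authors also deposited the log2 fold changes of their own DESeq2 comparisons. The authors' deposited p-values, raw and adjusted, stand in the same tables. The version, model formula and filters behind these comparisons are not given in the sources used here. Reads had been processed with fastp 0.23.2, HISAT2 2.2.1 and StringTie 1.3.1 on build GRCm39, per the submitters' processing notes. The annotation release and the strand setting used in counting are not given in the sources used here. The estimated counts were whole numbers, and low values piled up at multiples of 4. Such values were 1.53 to 1.73 times as frequent as their neighbours across the libraries, with a median of 1.63. Count-based precision is therefore overstated for weakly expressed genes, and the counts divided by 4 were run as an alternative. Total counts per library ran from 88995300 to 131545000, estimates and not numbers of sequenced fragments.

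Of the 56941 genes in the table, 33118 had a count in at least 1 library. Symbols came from the authors' deposited tables for 21595 genes and from the reference annotation alone for 30432, and 4914 had none. Of the genes tested, 642 had no symbol. The reference annotation available here was on build GRCm38, so it served for gene names and for the order of genes along a chromosome, and no coordinates are given. Reads shared between closely related genes could not be traced in the tables. The values of the Cyp2a4 and Cyp2a5, Saa1 and Saa2, Serpina1 and Nat8 families, of the amylases and of the histone gene Hist1h2al are uncertain for that reason.

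The estimated counts were rounded to whole numbers and analysed with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr on the 8 groups (minimum count 10, minimum total 15), which left 20514 genes. With TMM scaling, one quasi-likelihood model with robust estimation was fitted to all 24 libraries with 8 group means, and contrasts were tested with the quasi-likelihood F-test. Benjamini-Hochberg adjusted p-values under 0.05 were counted as calls, for each contrast over all genes tested. Every adjusted p given for a gene without another tool's name is from this model. Fold changes are given on the log2 scale with their standard error (SE), and levels as CPM, counts scaled by the library total and its TMM factor, with the standard deviation (SD) over the 3 libraries of a group. For fold changes against a group with 0 counts in all its libraries, a floor of 3 counts per library was used and the fold is given as a lower bound. Intervals and floors cover counting error only.

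The contrasts were KO against WT and LKO against F, each as the mean over both times and at each time. CT14 against CT2 was tested within each of the 4 genotypes. The difference of the time effect was tested between KO and WT and between LKO and F. The KO effect was also set against the LKO effect, and F against WT as the mean over both times. The overlap of KO and LKO calls was tested with Fisher's exact test, two-sided, separately for each direction. The part of a time difference kept in LKO was compared between sets of genes with a two-sided permutation test of the medians (100000 permutations).

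Named lists of genes were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2, with a preset correlation between genes of 0.01, and adjusted over the 33 lists with at least 5 tested members. The lists covered clock genes with E-box control and with RORE control, xenobiotic metabolism, bile acids, cholesterol synthesis, lipogenesis, fatty acid oxidation, glucose metabolism, NAD metabolism, NRF2 and redox genes, heat shock, endoplasmic reticulum stress, the growth hormone axis, male-biased and female-biased genes, the acute phase, inflammation, interferon-stimulated genes, the cell cycle, immediate early genes, cold-inducible genes, mitochondrially encoded genes and ribosomal proteins. They also covered markers of hepatocytes, Kupffer cells and macrophages, endothelium, stellate cells and fibroblasts, cholangiocytes, lymphocytes, neutrophils, erythroid cells, adipocytes and pancreatic acinar cells. A list of sex chromosome genes was read per library only. Of 577 list members, 2 (Tf and Ahsp) found no match. Each list was also tested with camera with the correlation estimated from the data, and with fry, which tests whether the genes of a list move, on balance, one way. For each list the number of its members called over all genes and the number called when adjusted over the list alone were counted.

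Genes were named by a rule. A gene had to have an adjusted p under 0.05, an absolute log2 fold change of at least 1 and a mean CPM of at least 1 over the compared libraries. Every library of one group also had to lie above every library of the other, at each time for the mean comparisons, a condition dropped for differences between effects. Genes were then ranked by absolute log2 fold change. The 6 highest and 6 lowest were taken for the mean comparisons of KO and LKO, the 5 highest and 5 lowest for time in WT and in F, for the KO effect against the LKO effect and for F against WT, and the 3 highest and 3 lowest elsewhere. Gene models without a proper name were passed over. Bmal1, all members of both clock lists and up to 4 members of any other list with the smallest adjusted p were also named, with members that show what did not pass. The lists, the contrasts, the naming rule and the alternatives up to leave-one-out were fixed before the data were examined.

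Alternatives chosen before the data were examined were RLE factors, no count filter, a filter of at least 1 CPM in at least 3 libraries, DESeq2 1.42.0 on the same counts, limma-trend on log2 of TPM with a pseudocount of 1, a fit of only the groups compared, the replicate number as a block, and leaving out each library in turn. Alternatives added after the data had been seen were the counts divided by 4, fits without libraries that stood apart, held pancreatic transcripts or held spermatid transcripts, spermatid transcripts as a covariate, and leaving out each library in turn for lists that held with an estimated correlation. The spermatid genes formed a list of 27 that was written after the calls had been seen.

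The model was tested on simulated data with 3 libraries in each of 8 groups and 200 genes changed in KO, equal parts by 2-fold and by 4-fold, and with the cholesterol list raised 1.5-fold. For KO against WT as the mean over both times, edgeR recovered 42% of the genes changed 2-fold and 73% of those changed 4-fold, and 9 of its 127 calls were unchanged genes. For KO against WT at CT2 it recovered 23% and 63%, at CT14 21% and 63%, and for the KO effect against the LKO effect 22% and 65%. It made 0 calls where nothing had been changed, in LKO against F as the mean, in time in WT and in the difference of the time effect between KO and WT. DESeq2 called there 19, 22 and 24 unchanged genes in those 3 contrasts, and limma-trend, run on log2 CPM, 0. In the simulation of KO against WT, camera with the preset correlation called the raised list and 0 others. Regrouping the real libraries at random gave more list calls, so the list results below are given with the estimated correlation as well.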

Results

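Transcripts of mouse liver were measured by RNA-seq in animals that lacked the clock transcription factor BMAL1 throughout the body or only in cells with Albumin-Cre activity, which in the liver are chiefly hepatocytes. Global knockouts (KO) were set against wild-type (WT) mice on a C57BL/6J background. Liver-specific knockouts (LKO) were set against mice with floxed Bmal1 alleles and no Cre (F). Livers were collected at circadian time CT2, early in the subjective day, and at CT14, early in the subjective night. Each of the 8 groups had 3 libraries, 24 in all, with total counts between 88995300 and 131545000 per library. After a filter on low counts, 20514 genes were tested. Nothing in the labels says whether the replicates were separate animals, and if they were not, the p-values measure only the spread between these samples.

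Libraries of a group resembled each other, with Pearson correlations across genes of 0.933 to 0.973 on the log2 scale between replicates. The first principal component, with 23.5% of the variance, parted WT and KO from F and LKO. The second, with 12.8%, parted both controls from both knockouts. Several libraries carried transcripts that their groups did not share. A list of 27 genes known from spermatids was chosen after such genes had been seen among the calls. Of these genes, such as the protamines Prm1 and Prm2 that package sperm DNA, the summed level was 12.2 to 47.8 CPM in 14 libraries and at most 2.16 CPM in the other 10. The 14 were all F and LKO libraries and the KO libraries CT2 replicate 2 and CT14 replicate 1. In all, 128 of the tested genes were higher in each of these 14 libraries than in each of the 10, where chance would give 5.1e-05% of genes for a division fixed in advance. This division was drawn from the spermatid genes, and 21 of the 128 are on that list. Pancreatic enzyme transcripts were found in F CT2 replicate 3 (2539 CPM summed over 11 genes) and F CT14 replicate 3 (789 CPM), against at most 6.63 CPM elsewhere. Interferon-stimulated genes summed to 3811 CPM in KO CT14 replicate 3 and to between 387 and 955 CPM in all other libraries. F CT2 replicate 3, LKO CT2 replicate 3 and KO CT2 replicate 1 also had low levels of the Y-linked gene Ddx3y (3.86, 8.15 and 9.61 CPM against 25.7 to 48.5 CPM in the other 21). The first 2 of these had mitochondrial shares of 1.37% and 1.82% (2.11 to 4.92% in all others) and root mean square deviations from the group mean of 0.870 and 0.737 on the log2 scale (0.515 to 0.718). The labels give no sequencing batch.

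**Figure D1:**
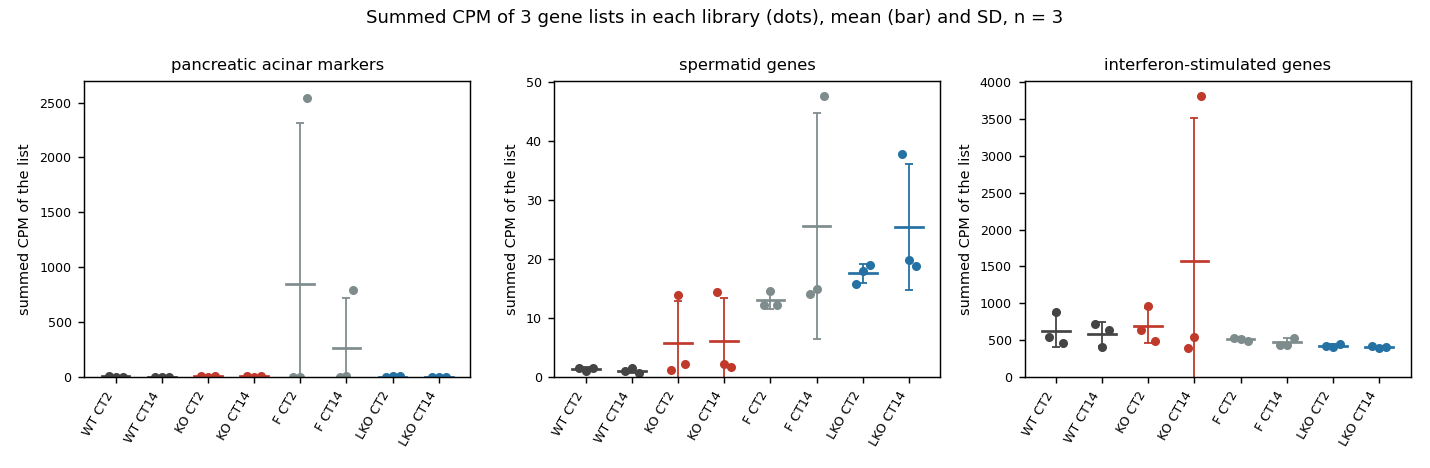
Summed CPM of pancreatic acinar markers, spermatid genes and interferon-stimulated genes in each of the 24 libraries (dots), with the group mean (bar) and SD, n = 3. Pancreatic markers stood out in F CT2 replicate 3 (2539 CPM) and F CT14 replicate 3 (789 CPM), and interferon-stimulated genes in KO CT14 replicate 3 (3811 CPM).

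Bmal1 itself (ENSMUSG00000055116) was read in every library first. In WT it stood at 30.7, 33.8 and 31.2 CPM at CT2 and at 6.46, 2.93 and 8.16 CPM at CT14. In KO it stood at 7.47, 7.15 and 7.57 CPM at CT2 and at 7.10, 6.66 and 7.53 CPM at CT14. F libraries had 29.1, 29.8 and 26.6 CPM at CT2 and 3.26, 14.97 and 10.4 CPM at CT14, and LKO libraries 7.63, 7.91 and 6.57 CPM and 5.96, 5.49 and 5.46 CPM. At CT2 Bmal1 was therefore lower in every knockout library than in every control library, with a log2 fold change of -2.11 ± 0.36 (SE, adjusted p = 0.00576) in KO and -1.95 ± 0.36 (adjusted p = 0.0112) in LKO. At CT14 the controls were themselves low, and neither KO (0.28 ± 0.35, adjusted p = 0.791) nor LKO (-0.76 ± 0.35, adjusted p = 0.436) differed from its control. The time difference of Bmal1 was -2.45 ± 0.37 in WT (adjusted p = 0.000431) and -0.06 ± 0.35 in KO (adjusted p = 1), and the difference between these was 2.39 ± 0.50 (adjusted p = 0.0215, and 0.0522 to 0.0600 without any 1 of WT CT2 replicate 2, WT CT14 replicate 2 and the 3 KO CT2 libraries). The LKO call at CT2 was lost without LKO CT2 replicate 1 (adjusted p = 0.0640) or LKO CT2 replicate 2 (adjusted p = 0.0600). The labels of knockout and control could thus be checked with this gene at CT2 and not at CT14.

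**Figure D2:**
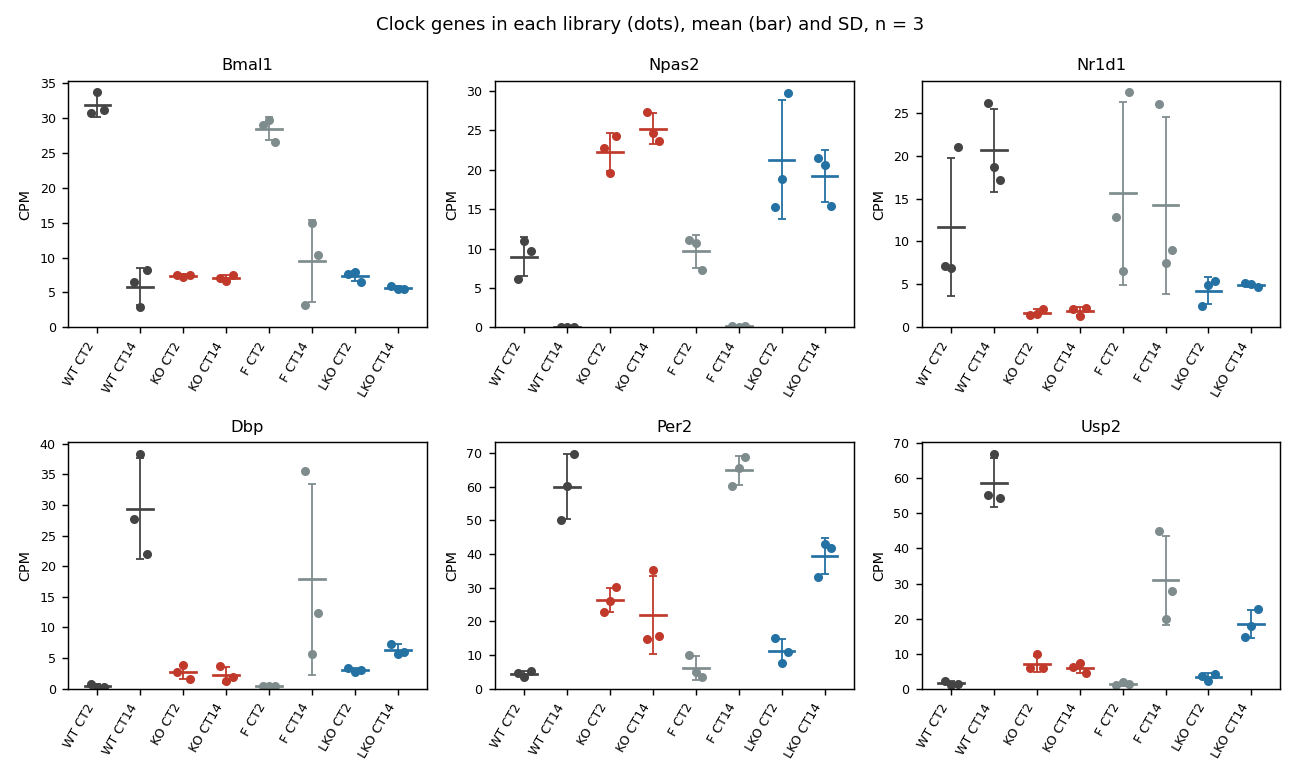
CPM of Bmal1, Npas2, Nr1d1, Dbp, Per2 and Usp2 in each library (dots), with the group mean (bar) and SD, n = 3. Npas2 averaged 0.0571 CPM in WT and 25.2 CPM in KO at CT14, and Usp2 58.8 CPM and 5.95 CPM.

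The comparison of KO with WT, as the mean of both times, asked which liver transcripts depended on BMAL1 anywhere in the body. The N-acetyltransferase gene Nat8 (ENSMUSG00000030004) fell 38.6-fold as the mean of both times (log2 -5.27 ± 0.43, adjusted p = 2.79e-07), with 26.7 ± 12.6 CPM (SD, n = 3) in WT and 0.700 ± 0.193 CPM in KO at CT2. The membrane peptidase gene Mme (ENSMUSG00000027820) fell 23.7-fold and the collagen gene Col27a1 (ENSMUSG00000045672) 10.1-fold. The water channel gene Aqp4 (-4.82 ± 0.68), the asparagine synthetase gene Asns (-3.88 ± 0.53) and the Nat8 relative Nat8f5 (-3.36 ± 0.49) fell as well. Npas2 (ENSMUSG00000026077), a paralogue of Clock and a partner of BMAL1, rose 32.7-fold (adjusted p = 9.79e-11). The neurotrophin receptor gene Ntrk2 (ENSMUSG00000055254) rose 50.4-fold as the mean of both times (0.437 ± 0.177 CPM in WT and 43.0 ± 23.3 CPM in KO at CT2), and the transmembrane channel-like gene Tmc5 114-fold. Tmc5 is among the 50 tested genes nearest to Bmal1 on its side and was higher in F than in WT as well. The homeobox gene Cdx4, near 0 in WT (0.106 ± 0.110 CPM at CT2 and 0 at CT14), stood at 2.92 ± 1.10 and 2.61 ± 1.11 CPM in KO. Tinag reached 2.34 ± 0.29 CPM and the estrogen sulfotransferase gene Sult1e1 7.04 ± 2.96 CPM at CT2 against 0.0171 ± 0.0297 and 0.0474 ± 0.0821 CPM in WT.

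In edgeR 1107 genes were called in this comparison, 638 higher and 469 lower in KO, of which 576 changed at least 2-fold. The calls of the 12 genes taken by the naming rule held when any single library was left out. Of the 638 genes higher in KO, 46 were among the 128 that followed the spermatid transcripts, and without the 2 KO libraries that held these transcripts 866 genes were called (461 higher, 405 lower). Among all tested genes 4.11% had their replicates fully separated at both times, where chance would give 0.5%. The authors' deposited table for this comparison has 1181 calls, of which 712 were shared in direction with those given here. On the TPM scale limma-trend placed more of its calls on the higher side (1363 of 1690).

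Of 25 tested genes of cholesterol synthesis, 14 were higher and 0 lower over all genes tested (16 and 0 when adjusted over the list alone), with a median log2 fold change of 0.69 and an adjusted p of 1.35e-12 with camera. With an estimated correlation the adjusted p = 0.259. Members included Hmgcs1, which makes the precursor of mevalonate (1.64 ± 0.29), Lss, which forms lanosterol (1.25 ± 0.21), Msmo1 (0.99 ± 0.20) and Nsdhl (0.86 ± 0.15). Of the 27 genes of fatty acid oxidation, 6 were lower and 1 higher (11 and 1 adjusted over the list alone). These included the carnitine carrier gene Slc25a20 (-0.74 ± 0.12), the fatty acid binding protein gene Fabp1 (-1.31 ± 0.25) and Acaa1b (-1.65 ± 0.29), whereas Pdk4, which restrains pyruvate use, rose (1.96 ± 0.34). The list's adjusted p = 9.54e-06 became an adjusted p = 0.364 with an estimated correlation. In glucose metabolism 5 of 22 genes were lower and 2 higher (8 and 3 adjusted over the list alone, adjusted p = 0.0046). The liver glycogen synthase gene Gys2 (-1.48 ± 0.12), the glucose transporter gene Slc2a2 (-0.84 ± 0.14) and the pyruvate kinase gene Pklr (-0.89 ± 0.15) fell and the glucokinase regulator gene Gckr rose (0.72 ± 0.09). For that list the adjusted p = 0.179 with an estimated correlation. Lipogenesis had 3 of 21 genes lower and 1 higher (9 and 1 adjusted over the list alone, adjusted p = 0.00177, and adjusted p = 0.364 with an estimated correlation), with Thrsp at -1.36 ± 0.29.

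Acute phase genes, whose products the liver secretes in inflammation, had 6 of 21 higher and 0 lower (10 and 1 adjusted over the list alone), among them Lbp (1.61 ± 0.24), Cp (1.23 ± 0.23) and Itih3 (1.05 ± 0.22). The adjusted p of 1.71e-05 became an adjusted p = 0.42 with an estimated correlation, and 1 WT library, CT2 replicate 1, had 61414 CPM summed over the list against 27905 and 26739 CPM in the other two of its group. Interferon-stimulated genes had 1 of 22 members higher (7 adjusted over the list alone, adjusted p = 0.0206, adjusted p = 0.698 with an estimated correlation), and that member, Rsad2, was not called without KO CT14 replicate 3 (adjusted p = 0.204).

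Of the 6 genes under RORE control 3 rose, among them Npas2 and Cry1 (1.22 ± 0.13), and 0 fell (3 and 0 adjusted over the list alone, adjusted p = 1.71e-05, adjusted p = 0.0798 with an estimated correlation). Of the 14 genes under E-box control, the nuclear receptor genes Nr1d1 (-3.11 ± 0.39) and Nr1d2 (-2.80 ± 0.23) and the repressor gene Bhlhe41 (-5.10 ± 0.85) fell and Cry2 rose (0.79 ± 0.11). The counts were 1 higher and 3 lower on either adjustment (adjusted p = 0.0162, adjusted p = 0.364 with an estimated correlation).

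Camera called heat shock (0 of 18 higher and 1 lower, 0 and 2 adjusted over the list alone, adjusted p = 0.42 with an estimated correlation), where the small heat shock protein gene Hspb1 fell (-2.70 ± 0.33). It called endoplasmic reticulum stress (1 of 21 higher and 2 lower on either adjustment, adjusted p = 0.438 with an estimated correlation), where the stress factor gene Atf5 rose (1.15 ± 0.19). It called immediate early genes (0 of 20 higher and 2 lower, 0 and 3 adjusted over the list alone, adjusted p = 0.395 with an estimated correlation), where Jun (-0.95 ± 0.14) and Klf10 (-1.02 ± 0.22) fell. It called mitochondrially encoded genes, 0 of 15 called (0 and 1 adjusted over the list alone), with an adjusted p = 0.593 with an estimated correlation. Ribosomal protein genes, with 0 of 30 called on either adjustment and a median of 0.22, had an adjusted p = 0.438 with an estimated correlation. Cholangiocyte markers had 2 of 10 higher on either adjustment (adjusted p = 0.364 with an estimated correlation), among them the duct regulator gene Sox9 (1.26 ± 0.26). Lymphocyte markers had 2 of 15 lower (3 adjusted over the list alone, adjusted p = 0.438 with an estimated correlation), and neutrophil markers 1 of 11 higher on either adjustment (adjusted p = 0.593 with an estimated correlation).

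Other lists were not called by camera. Xenobiotic metabolism had members on both sides, 4 of 27 higher and 7 lower (6 and 9 adjusted over the list alone), among them the cytochrome P450 genes Cyp2c55 (4.16 ± 0.56) and Cyp2c29 (1.01 ± 0.15), which rose, and Cyp2a5 (-2.94 ± 0.44) and the carboxylesterase gene Ces2a (-0.89 ± 0.16), which fell. Its adjusted p = 0.33, with a median of -0.12 and a mean of 0.01 on the log2 scale. Bile acid genes had 3 of 21 higher and 1 lower on either adjustment (adjusted p = 0.574), with a median of -0.01 and a mean of 0.03. The bile salt export pump gene Abcb11 rose (0.84 ± 0.14) and the transporter gene Abcc4 fell (-1.26 ± 0.24). Of 21 NRF2 and redox genes 3 were higher and 4 lower (5 and 6 adjusted over the list alone, adjusted p = 0.437), with the glutathione transferase gene Gstm3 at 2.10 ± 0.30. Cell cycle genes had 2 of 25 higher and 1 lower (3 and 4 adjusted over the list alone, adjusted p = 0.362). Cdkn1a, the cyclin-dependent kinase inhibitor p21, rose (2.22 ± 0.26) and the ribonucleotide reductase gene Rrm2 fell (-1.10 ± 0.25). Hepatocyte markers had 1 of 9 higher and 1 lower on either adjustment (adjusted p = 0.362), and the albumin gene Alb fell (-0.87 ± 0.17). Female-biased genes had 5 of 23 higher and 1 lower (8 and 4 adjusted over the list alone, adjusted p = 0.158), with a median of -0.22 and a mean of 0.997. Male-biased genes had 1 of 20 higher, Elovl3 (2.16 ± 0.48), and 1 lower (2 and 3 adjusted over the list alone, adjusted p = 0.104).

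Of 14 NAD metabolism genes 0 were higher and 1, Nmrk1 (-0.93 ± 0.21), was lower (0 and 3 adjusted over the list alone, adjusted p = 0.305). The growth hormone axis had 0 of 12 genes called on either adjustment (adjusted p = 0.35). Inflammation genes had 2 of 21 lower (3 adjusted over the list alone, adjusted p = 0.437), and cold-inducible genes 1 of 5 higher (2 adjusted over the list alone, adjusted p = 0.0623). Among markers of other cells, Kupffer cells and macrophages had 0 of 14 called on either adjustment (adjusted p = 0.133) and endothelium 0 higher and 1 lower of 14 (1 and 1 adjusted over the list alone, adjusted p = 0.28). Stellate cells and fibroblasts had 0 of 14 higher and 1 lower (0 and 2 adjusted over the list alone, adjusted p = 0.28), and erythroid cells 0 of 7 called (0 and 1 adjusted over the list alone, adjusted p = 0.396). Adipocyte markers had 1 of 5 lower on either adjustment (adjusted p = 0.104) and pancreatic acinar markers 0 of 11 called on either adjustment (adjusted p = 0.44).

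At CT2, when BMAL1 targets are near their low point in WT, the comparison of KO with WT asked what its loss changed at that phase. Under E-box control the period gene Per2 rose from 4.49 ± 0.92 to 26.4 ± 3.7 CPM (n = 3, log2 2.55 ± 0.36, adjusted p = 0.000796), Per3 by 1.94 ± 0.33 on the log2 scale, and the PAR bZIP factor gene Tef from 21.8 ± 2.2 to 79.0 ± 5.3 CPM. The deubiquitinase gene Usp2 (2.21 ± 0.35) and Cry2 (adjusted p = 0.000229) rose too, whereas Nr1d2 fell (-1.83 ± 0.31), a call lost without KO CT2 replicate 1 (adjusted p = 0.0526). The list had 7 of 14 higher and 2 lower (9 and 3 adjusted over the list alone), with an adjusted p of 6.15e-09, and the adjusted p = 0.0117 with an estimated correlation. Among those that did not pass were Per1 (adjusted p = 0.185), Ciart (2.43 ± 1.16, adjusted p = 0.554), Hlf (adjusted p = 0.663) and Bhlhe40 (adjusted p = 0.487). Cry1 (1.24 ± 0.19) and Npas2 (1.31 ± 0.28) rose among the 6 genes under RORE control (3 higher and 0 lower, 3 and 1 adjusted over the list alone, adjusted p = 0.386 with an estimated correlation), and Npas2 was uncalled without any of 5 of the 6 libraries.

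Outside the clock, Nat8 (-5.26 ± 0.61), Mme (-3.79 ± 0.61) and the dicarboxylate transporter gene Slc13a2 (-2.83 ± 0.43) fell at CT2, and Ntrk2 rose (6.61 ± 1.06, adjusted p = 0.00536). Cyp2a4 fell further (-7.68 ± 1.59, adjusted p = 0.0359), a call lost without any 1 of 4 of the 6 libraries (adjusted p of 0.0940 to 0.180). Tmc5 (5.73 ± 1.09) and Elfn1 (4.83 ± 0.96) followed, but Tmc5 was not called without WT CT2 replicate 3 (adjusted p = 0.0919) or KO CT2 replicate 3 (adjusted p = 0.0556), nor Elfn1 without these or WT CT2 replicate 1 (adjusted p of 0.105 to 0.124). In edgeR 106 genes were called at CT2 (67 higher, 39 lower), and 14.04% of all tested genes had separated replicates, where chance would give 10%. The count fell to 56, 62, 56 and 50 without WT CT2 replicate 1, 2 or 3 or KO CT2 replicate 1, rose to 117 without the 2 KO libraries with spermatid transcripts, and was 335 in the authors' deposited table. DESeq2 called 394 genes, and limma-trend 196 (156 higher, 40 lower).

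At CT14, when many E-box genes are high in WT, the comparison of KO with WT asked the same at the opposite phase. Npas2 stood at 0.0571 ± 0.0187 CPM in WT and 25.2 ± 1.9 CPM in KO, a 432-fold rise (log2 8.75 ± 0.41, n = 3, adjusted p = 4.66e-11). The circadian repressor gene Ciart fell from 11.5 ± 5.1 to 0.157 ± 0.087 CPM (-6.18 ± 1.10), Dbp from 29.4 ± 8.2 to 2.25 ± 1.26 CPM and Usp2 from 58.8 ± 7.1 to 5.95 ± 1.35 CPM. Per3 (-2.71 ± 0.33), Nr1d2 (-3.78 ± 0.34) and Tef (-1.25 ± 0.18) fell too. Of the 14 genes under E-box control 10 were lower and 0 higher (12 and 0 adjusted over the list alone, adjusted p = 5.93e-18, adjusted p = 0.000295 with an estimated correlation). Of the 6 under RORE control 3 were higher on either adjustment (adjusted p = 0.0177 with an estimated correlation), with Cry1 at 1.20 ± 0.19. Per3, Tef and Usp2 were thus higher in KO at CT2 and lower at CT14, whereas Nr1d2 was lower at both (at CT2 adjusted p = 0.0526 without KO CT2 replicate 1) and Cry2, higher at CT2, was at 0.28 at CT14 (adjusted p = 0.397).

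In glucose metabolism 7 of 22 genes were lower and 2 higher in KO (9 and 3 adjusted over the list alone, adjusted p = 1.56e-05, adjusted p = 0.0123 with an estimated correlation), led by Gys2 (-2.49 ± 0.18) and Pklr (-2.05 ± 0.22). Thrsp, a regulator of lipogenesis, fell from 2011 ± 242 to 131.6 ± 68.2 CPM and the phosphatidate phosphatase gene Lpin1 by 3.27 on the log2 scale. Of the 21 lipogenesis genes 6 were lower and 1 higher (12 and 2 adjusted over the list alone, adjusted p = 0.189 with an estimated correlation). Cholesterol synthesis had 12 of 25 genes higher and 0 lower (17 and 0 adjusted over the list alone, adjusted p = 0.198 with an estimated correlation), and Hmgcs1 rose by 2.88 ± 0.43. Heat shock genes had 3 of 18 lower (12 adjusted over the list alone, adjusted p = 0.134 with an estimated correlation), with Hspb1 at -2.93 ± 0.47 and the co-chaperone gene Dnajb1 at -1.48 ± 0.31. Acute phase genes had 7 of 21 higher (10 adjusted over the list alone, adjusted p = 0.344 with an estimated correlation), among them Lbp (2.46 ± 0.36) and the fibrinogen genes Fga (1.60 ± 0.28) and Fgb (1.55 ± 0.28). Interferon-stimulated genes had 7 of 22 higher (9 adjusted over the list alone, adjusted p = 0.681 with an estimated correlation). Of these, Rsad2 (5.25 ± 1.10), Isg15 (3.90 ± 0.98), Mx2 and Rigi had adjusted p of 0.0694, 0.865, 0.404 and 0.269 without KO CT14 replicate 3, the library with 3811 CPM of such transcripts.

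In edgeR 1089 genes were called at CT14, 647 higher and 442 lower, with 25.9% of tested genes separated where chance would give 10%. The authors' deposited table has 1860 calls, 928 of them shared in direction, and limma-trend called 1397 (1058 higher, 339 lower). Other large changes were those of Cyp2a4, a steroid hydroxylase gene (-7.62 ± 1.51), Aqp4 (-6.44 ± 1.04) and Cdx4, at least 101-fold higher than a WT group at 0. The histone gene Hist1h2al (9.96 ± 2.41) was not called without WT CT14 replicate 1, 2 or 3 (adjusted p = 0.0978, 0.106 and 0.0811). The count was 632 without WT CT14 replicate 2, 795 without the 2 KO libraries with spermatid transcripts and 1728 without F CT2 replicate 3 and LKO CT2 replicate 3.

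The comparison of LKO with F, as the mean of both times, asked which transcripts depended on BMAL1 in the Cre-expressing cells of the liver. Nat8 (24.9-fold), Mme (16.4-fold) and Cyp17a1, the steroid 17-hydroxylase gene (21.6-fold), fell, the last with 35.8 ± 5.2 CPM (SD, n = 3) in F and 1.51 ± 0.27 CPM in LKO at CT14. Pnpla3, a lipid droplet hydrolase gene, fell by 3.74 on the log2 scale (SE 0.66). Npas2 rose 18.6-fold (adjusted p = 4.91e-10), the HMG-box gene Tox2 26.5-fold (0.685 ± 0.200 CPM in F and 18.0 ± 4.5 CPM in LKO at CT2), and Cyp2c55 26.7-fold. The defensin gene Defb1 (4.64 ± 0.61) and Ntrk2 (4.04 ± 0.67) rose as well. The acute phase genes Saa1 (-4.52 ± 1.07) and Saa2 (-5.19 ± 1.36) fell and the zinc finger gene Zfp37 rose (4.74 ± 1.12), but these calls were lost without any 1 of 8, 10 and 7 of the 12 libraries, with adjusted p up to 0.0932, 0.143 and 0.0989. In edgeR 642 genes were called, 348 higher and 294 lower, of which 333 changed at least 2-fold, and 3.11% of tested genes were separated at both times where chance would give 0.5%. The authors' deposited table has 584 calls, and limma-trend on the TPM scale placed 1469 of its 1645 calls on the higher side. The count was 415 without LKO CT14 replicate 2, 419 without LKO CT14 replicate 3 and 479 without the 2 F libraries with pancreatic transcripts.

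Of the 6 RORE genes 3 were higher and 0 lower in LKO on either adjustment (adjusted p = 7.15e-07, adjusted p = 0.0303 with an estimated correlation), with Cry1 at 1.49 ± 0.13. Of the 14 genes under E-box control, Cry2 (0.69 ± 0.11) and Tef (0.74 ± 0.12) rose and Nr1d1 (-1.69 ± 0.37) and Nr1d2 (-1.54 ± 0.22) fell (2 and 4 adjusted over the list alone). That list was not called (adjusted p = 0.478), with a median of 0.20 and a mean of -0.24. Cholesterol synthesis had 10 of 25 genes higher and 0 lower (15 and 0 adjusted over the list alone, adjusted p = 5.58e-10, adjusted p = 0.311 with an estimated correlation), with Acat2 at 0.68 ± 0.14 and Cyp51 at 0.79 ± 0.17. Lipogenesis had 7 of 21 genes lower and 1 higher (10 and 2 adjusted over the list alone, adjusted p = 0.233 with an estimated correlation). The acetyl-CoA carboxylase gene Acacb (-1.15 ± 0.21), Thrsp (-1.47 ± 0.29) and the malic enzyme gene Me1 (-1.10 ± 0.22) were among those that fell. Acute phase genes had 7 of 21 lower and 0 higher in LKO (13 and 0 adjusted over the list alone, adjusted p = 1.72e-08, adjusted p = 0.332 with an estimated correlation), with Saa4 at -1.70 ± 0.27. The summed level was 39501 to 59596 CPM in F at CT2 and 18813, 39738 and 43945 CPM in F CT14 replicates 1 to 3, against 22303 to 39511 CPM in LKO. WT CT2 replicates 2 and 3 and WT CT14 had 19241 to 27905 CPM. Neutrophil markers summed to 52.8 CPM in F CT2 replicate 3, 71.8 CPM in F CT14 replicate 2 and 54.9 CPM in LKO CT2 replicate 2, and to 4.01 CPM in F CT14 replicate 1. Endoplasmic reticulum stress genes had 2 of 21 lower (6 lower and 1 higher adjusted over the list alone, adjusted p = 0.233 with an estimated correlation), with Asns at -2.84 ± 0.49. Glucose metabolism had 5 of 22 genes lower and 1 higher (5 and 2 adjusted over the list alone, adjusted p = 0.311 with an estimated correlation), with the ketohexokinase gene Khk at -0.81 ± 0.12. Cdkn1a (2.89 ± 0.27) and Elovl3, a male-biased fatty acid elongase gene (3.01 ± 0.50), rose and Alb fell (-0.97 ± 0.17). Pancreatic acinar markers had 5 of 11 genes lower (11 adjusted over the list alone, adjusted p = 0.332 with an estimated correlation), and 0 of the 5 were called without F CT2 replicate 3 and F CT14 replicate 3. Camera called 17 lists in this comparison, and 1, the RORE genes, held with an estimated correlation, though not without any 1 of 3 of the 12 libraries (adjusted p up to 0.0567).

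At CT2 the comparison of LKO with F asked what the liver's own loss changed early in the day. The E-box genes Tef (2.11 ± 0.18, adjusted p = 1.93e-06), Wee1, a cell cycle kinase gene (2.10 ± 0.29), Per3 (2.03 ± 0.33) and Cry2 (1.16 ± 0.16) rose. Tef went from 17.3 ± 4.6 to 74.8 ± 9.2 CPM (SD, n = 3). The list had 5 of 14 higher and 0 lower (9 and 3 adjusted over the list alone, adjusted p = 6.31e-08, adjusted p = 0.0283 with an estimated correlation). The latter was lost without any 1 of 5 of the 6 libraries (adjusted p up to 0.140). Cry1 (1.83 ± 0.19) rose among the 6 RORE genes (2 higher and 0 lower, 3 and 0 adjusted over the list alone, adjusted p = 0.0718 with an estimated correlation). Of 21 endoplasmic reticulum stress genes 0 were called over all genes and 11 lower when adjusted over the list alone (adjusted p = 2.78e-12, adjusted p = 0.0321 with an estimated correlation). The latter was lost without any 1 of 5 of the 6 libraries, with the highest adjusted p = 0.422 without F CT2 replicate 3, which held 2539 CPM of pancreatic transcripts. Mme (-4.21 ± 0.62), Nat8 (-4.19 ± 0.57) and Col27a1 (-2.39 ± 0.33) fell and Tox2 rose (4.71 ± 0.34). Cyp2c55 (4.22 ± 0.78) and Defb1 (4.19 ± 0.84) were called with all libraries, and not without any 1 of 4 and 5 of the 6 (adjusted p up to 0.0828 and 0.107). The acetate-activating enzyme gene Acss2 rose by 1.62 ± 0.24.

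In edgeR 82 genes were called at CT2 (56 higher, 26 lower), with 10.6% of tested genes separated where chance would give 10%, and 184 stand in the authors' deposited table. The count was 44, 47 and 47 without F CT2 replicate 1, LKO CT2 replicate 1 or LKO CT2 replicate 2, and 155 and 133 without F CT2 replicate 3 or LKO CT2 replicate 3. DESeq2 called 436 genes (229 higher, 207 lower), limma-trend 219 (190 higher, 29 lower), and a fit of these groups alone 1 (1 higher, 0 lower).

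At CT14 the comparison of LKO with F asked the same early in the night. Npas2 rose 157-fold, from 0.120 ± 0.063 to 19.2 ± 3.3 CPM (SD, n = 3, adjusted p = 3.42e-10), and the lysyl oxidase-like gene Loxl4 52.9-fold, from 1.05 ± 0.40 to 55.8 ± 16.1 CPM. The homeobox gene Pitx3 (6.25 ± 1.09), Elovl3 (5.07 ± 0.77) and Cdkn1a (4.68 ± 0.41) rose too. Nat8 (-5.09 ± 0.60) and Pnpla3 (-6.18 ± 1.03) fell, and the G-protein regulator gene Rgs16 (-6.67 ± 1.38) was called only with all 3 LKO libraries (adjusted p = 0.0821, 0.112 and 0.0933 without LKO CT14 replicate 1, 2 or 3). Per3 (-1.74 ± 0.32) and Nr1d2 (-2.15 ± 0.31) were among 3 E-box genes that fell (7 adjusted over the list alone, adjusted p = 0.0204 with an estimated correlation). Dbp (-1.48 ± 0.51, adjusted p = 0.192) and Per2 (-0.72 ± 0.34, adjusted p = 0.448) did not pass. RORE genes had 2 of 6 higher on either adjustment (adjusted p = 0.0204 with an estimated correlation). Lipogenesis had 7 of 21 genes lower and 0 higher (15 and 1 adjusted over the list alone, adjusted p = 4.8e-13, adjusted p = 0.0204 with an estimated correlation), with Acacb at -2.51 ± 0.30 and Thrsp at -2.76 ± 0.43. Without F CT14 replicate 1 the 3 list calls with an estimated correlation were lost (adjusted p = 0.0655 for E-box genes and lipogenesis, 0.0891 for RORE genes). Gys2 fell by 1.53 on the log2 scale. In edgeR 354 genes were called (167 higher, 187 lower), with 23.6% of genes separated where chance would give 10%, and the authors' deposited table has 1620. The count was 199, 195, 171 and 192 without F CT14 replicate 3 or LKO CT14 replicate 1, 2 or 3, and 669 without F CT2 replicate 3 and LKO CT2 replicate 3. DESeq2 called 781 genes and limma-trend 860 (712 higher, 148 lower).

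**Figure D3:**
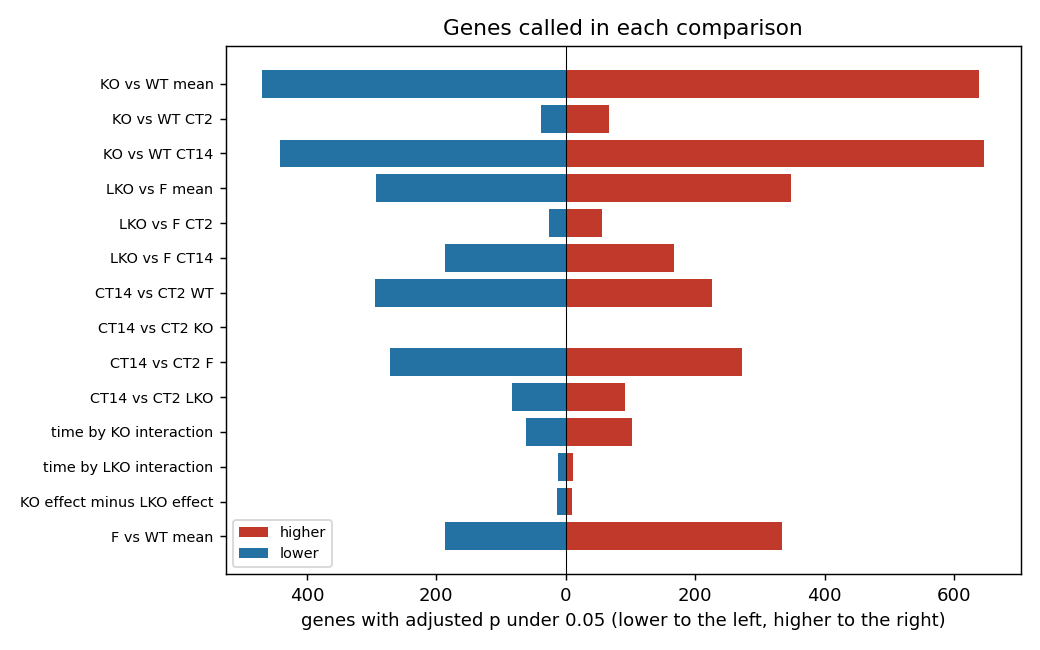
Number of genes with an adjusted p under 0.05 in edgeR in each of the 14 comparisons, lower to the left and higher to the right of 0. The mean comparison of KO with WT had 638 genes higher and 469 lower, and CT14 against CT2 in KO had 0.

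CT14 was compared with CT2 in WT and in F to show which transcripts differed with time where the clock was intact. In WT the E-box gene Dbp rose 57.7-fold, from 0.506 ± 0.296 to 29.4 ± 8.2 CPM (SD, n = 3, adjusted p = 9.38e-06), Usp2 37.9-fold, Per3 26.7-fold, and Ciart by 8.47 ± 1.27 on the log2 scale. Per1 (4.09 ± 0.68), Per2 (3.74 ± 0.38), Tef (2.88 ± 0.19), Wee1 (2.83 ± 0.29) and Nr1d2 (2.49 ± 0.32) rose as well. In F Dbp rose 38.3-fold, Per3 23.96-fold, Usp2 22.0-fold and Ciart by 5.95 ± 1.11. Among the 14 genes 12 were higher and 0 lower in WT and in F (12 and 13 higher adjusted over the list alone, adjusted p = 1.48e-06 and 1.62e-05 with an estimated correlation). Npas2 fell 153-fold in WT and 79.2-fold in F. The extracellular matrix genes Loxl4 (-3.94 ± 0.64 in WT, -4.80 ± 0.66 in F) and Spon2 (-3.83 ± 0.42 in WT, -3.37 ± 0.41 in F) fell in both, as did Elovl3 (-3.51 ± 0.72 in WT, -4.06 ± 0.74 in F), whose call in WT was lost without WT CT14 replicate 2 or 3 (adjusted p = 0.0659 and 0.0627). Dhrs9 (-5.69 ± 1.26) and Pitx3 (-4.39 ± 1.03) in WT were lost without any 1 of 4 and 5 of the 6 libraries (adjusted p up to 0.0817 and 0.129). Mfsd2a (4.95 ± 0.97) was lost without WT CT2 replicate 2 (adjusted p = 0.0530). In F, Pitx3 (-4.99 ± 1.03) was lost without F CT14 replicate 1 or 3 (adjusted p = 0.0771 and 0.0683), and Acot3 (4.76 ± 1.07) without any 1 of 3 libraries, F CT2 replicates 1 and 2 and F CT14 replicate 2 (adjusted p of 0.0660 to 0.0835).

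In WT 7 of 22 glucose genes were higher and 1 lower at CT14 (10 and 1 adjusted over the list alone, adjusted p = 0.00057 with an estimated correlation), with Gys2 at 1.92 ± 0.18, the glucose-6-phosphate transporter gene Slc37a4 at 1.63 ± 0.19 and Pklr at 1.82 ± 0.22. In F 8 were higher and 0 lower (8 and 2 adjusted over the list alone, adjusted p = 0.0484 with an estimated correlation, lost without any 1 of the 6 libraries, 0.0521 to 0.135), with Gys2 at 1.59 ± 0.17. Heat shock genes had 7 of 18 higher in WT (15 adjusted over the list alone, adjusted p = 0.0447 with an estimated correlation, lost without any 1 of 5 of the 6 libraries, up to 0.136) and 5 in F (8 adjusted over the list alone, adjusted p = 0.267 with an estimated correlation), with the chaperone gene Hsph1 at 2.06 ± 0.38 in WT. Thrsp rose by 4.64 ± 0.47 in WT and 3.45 ± 0.44 in F. Lipogenesis as a whole had 3 of 21 higher and 1 lower in WT (10 and 1 adjusted over the list alone, adjusted p = 0.148 with an estimated correlation) and 4 and 0 in F (12 and 1 adjusted over the list alone, adjusted p = 0.213 with an estimated correlation). Xenobiotic genes had 6 of 27 higher in WT and 7 in F (9 higher and 1 lower and 12 higher adjusted over the list alone, adjusted p = 0.146 and 0.132 with an estimated correlation), among them the P450 reductase gene Por (2.13 ± 0.34 in WT) and the heme synthesis gene Alas1 (3.01 ± 0.57 in F). In edgeR 521 genes were called in WT (226 higher, 295 lower) and 545 in F (273 higher, 272 lower), with 21.03% and 19.2% of tested genes separated where chance would give 10%. The authors' deposited table has 1102 and 409. The WT count was 335, 332 and 270 without WT CT2 replicate 1, WT CT2 replicate 2 or WT CT14 replicate 2, and 944 without F CT2 replicate 3 and LKO CT2 replicate 3. The F count was 341, 240, 318 and 301 without F CT2 replicate 3 or F CT14 replicate 1, 2 or 3, 207 without the 2 F libraries with pancreatic transcripts, and 33 in a fit of these groups alone.

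The same time comparison in KO asked what time difference was left without BMAL1 in any cell. In KO no gene was called by edgeR between CT14 and CT2, and the smallest adjusted p was 0.624. There were 753 genes with an unadjusted p under 0.05, DESeq2 called 38 (27 higher, 11 lower), limma-trend 1, and 32 stand in the authors' deposited table. Dbp was at 2.70 ± 1.10 and 2.25 ± 1.26 CPM (SD, n = 3), Npas2 at 22.2 ± 2.4 and 25.2 ± 1.9 CPM and Per2 at 26.4 ± 3.7 and 21.9 ± 11.5 CPM. The log2 difference was -0.27 for Dbp, 0.18 for Npas2 and -0.27 for Per2, each with an adjusted p of 1. The count was 2, 8 and 1 without KO CT2 replicate 2, KO CT2 replicate 3 or KO CT14 replicate 1, and 4 without the 2 KO libraries with spermatid transcripts. Camera called the acute phase, interferon and immediate early lists, each with an adjusted p = 0.962 with an estimated correlation.

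The time difference was also compared between KO and WT. Usp2 (-5.51 ± 0.50, adjusted p = 3.71e-06) and Dbp (-6.12 ± 0.77) had a lower time difference in KO than in WT. So did Per3 (-4.65 ± 0.47), Per2 (-4.01 ± 0.49), Tef (-3.11 ± 0.25) and Wee1 (-2.84 ± 0.39). Npas2 (7.44 ± 0.48) had a higher one (3 libraries in each of the 4 groups). Among the genes under E-box control 9 of 14 were lower and 0 higher in this test (13 and 0 adjusted over the list alone, adjusted p = 5.29e-06 with an estimated correlation). Thrsp (-5.15 ± 0.61), Gys2 (-2.01 ± 0.24) and Pklr (-2.31 ± 0.30) behaved alike, and glucose metabolism had 4 of 22 genes lower (6 lower and 2 higher adjusted over the list alone, adjusted p = 0.00369 with an estimated correlation). Nckap5 (4.80 ± 0.72) differed in the other direction. In edgeR 164 genes were called (103 higher, 61 lower), 101 without WT CT14 replicate 2, 311 without F CT2 replicate 3 and LKO CT2 replicate 3, and 85 (46 higher, 39 lower) without the 2 KO libraries with spermatid transcripts. On the TPM scale limma-trend called 143 (67 higher, 76 lower). Ciart (-8.61 ± 1.55) was not called without those 2 (adjusted p = 0.0694), and Dhrs9 (6.89 ± 1.57) was not called without any 1 of 10 of the 12 libraries (adjusted p up to 0.135).

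CT14 was compared with CT2 in LKO to show what time difference was left where BMAL1 was lost from the Cre-expressing cells and other tissues kept it. Usp2 rose 5.59-fold, from 3.31 ± 1.04 to 18.5 ± 4.0 CPM (SD, n = 3, adjusted p = 0.00311), while Acacb (-2.03 ± 0.30) and Acss2 (-1.64 ± 0.24) fell. These calls held without any single library. Chac1, a glutathione-degrading enzyme gene, fell (-2.84 ± 0.47) and was lost without LKO CT14 replicate 2 (adjusted p = 0.123). The other genes taken by the naming rule were each lost without at least 4 of the 6 libraries in turn. They were the lower genes Cdc42ep5 (-2.93 ± 0.54) and Nr4a1 (-2.42 ± 0.55) and the higher genes Noct (2.63 ± 0.55) and Plin4 (2.53 ± 0.55), with adjusted p up to 0.152, 0.233, 0.140 and 0.201. Per2 (1.80 ± 0.35, adjusted p = 0.0299) was called and lost without any 1 of 4 libraries (adjusted p up to 0.135), while Dbp (1.06, adjusted p = 0.411), Per1 (1.74, adjusted p = 0.219), Per3 (0.81, adjusted p = 0.271), Tef (0.34, adjusted p = 0.469) and Npas2 (-0.15, adjusted p = 0.935) did not pass. E-box genes had 3 of 14 higher and 0 lower (8 and 0 adjusted over the list alone, adjusted p = 3.53e-09, adjusted p = 0.0104 with an estimated correlation, 0.0626 without LKO CT2 replicate 1). Heat shock had 1 of 18 higher (8 adjusted over the list alone, adjusted p = 0.619 with an estimated correlation). In edgeR 174 genes were called (91 higher, 83 lower), with 20.7% of tested genes separated where chance would give 10%, and the authors' deposited table has 606. The count was 38, 17, 59, 39, 10 and 10 without each library in turn, in the order CT2 replicates 1 to 3 and CT14 replicates 1 to 3. DESeq2 called 691 genes and limma-trend 175 (117 higher, 58 lower).

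The time difference was then compared between LKO and F directly. Per3 (-3.77 ± 0.46, adjusted p = 0.000406) and Wee1 (-3.27 ± 0.40) rose less in LKO than in F (3 libraries in each of the 4 groups), and Npas2 (6.16 ± 0.45) and Cdkn1a (3.59 ± 0.52) differed in the other direction. Of the 14 E-box genes 4 were lower and 0 higher (10 and 0 adjusted over the list alone, adjusted p = 0.000284 with an estimated correlation). Lipogenesis had 2 of 21 genes lower (12 adjusted over the list alone, adjusted p = 0.0366 with an estimated correlation, lost without any 1 of 8 of the 12 libraries, up to 0.317). Dbp (-4.20 ± 0.75) and Loxl4 (4.92 ± 0.83) were lost without any 1 of 7 and 5 of the 12 libraries (adjusted p up to 0.0999 and 0.0917). In edgeR 23 genes were called (11 higher, 12 lower). The count was 55 and 57 without F CT2 replicate 3 or LKO CT2 replicate 3, 75 without both, and 12 to 15 without F CT14 replicate 3 or any 1 of the other 5 LKO libraries.

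Of the genes called for time in WT and in F, 254 were shared with the same sign, 135 higher and 119 lower at CT14, and 0 had opposite signs. Independent lists would share 3.01 and 3.91. Signed by the controls' direction, their median log2 time difference was 1.36 in WT, 1.27 in F, 0.49 in LKO and -0.01 in KO. The sign of the controls was kept by 225 of the 254 genes (88.6%) in LKO and by 118 (46.5%) in KO. Between LKO and KO 51 genes had a larger time difference toward the controls' direction in LKO and 2 in KO, adjusted over the list alone, and 7 differed over all genes tested. In LKO 36 of the 254 were called for time, and in KO 0.

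**Figure D4:**
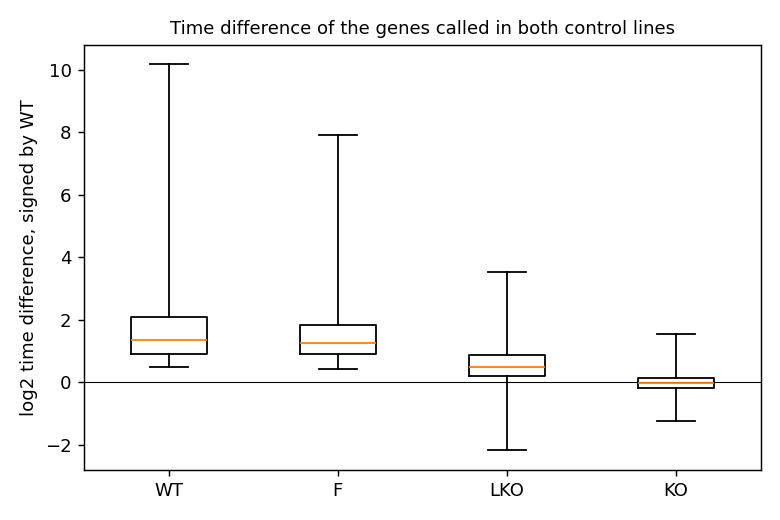
Log2 difference between CT14 and CT2, signed by its direction in WT, of the 254 genes called for time in both WT and F, with boxes for the quartiles, lines for the median and whiskers for the full range. Medians were 1.36 in WT, 1.27 in F, 0.49 in LKO and -0.01 in KO.

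The calls of KO against WT and of LKO against F, which share no library, were compared to see how much of the global effect recurred with loss in the liver. As the mean of both times, 222 genes were higher in both and 118 lower in both, where independent lists would share 10.8 and 6.72 (Fisher's exact test, p = 2.03e-257 and 7.49e-118), and 4 had opposite signs. Npas2, Nat8, Mme, Cdx4, Ntrk2, Cyp2c55, Defb1 and Tox2 were among the shared genes. Across genes, which are not independent replicates, the log2 fold changes correlated with r = 0.284 over all genes and 0.527 over the 1405 called in either comparison (Spearman's rho 0.278 and 0.687). At CT2, 32 genes were higher and 7 lower in both, and at CT14 137 and 96. Without the 2 KO libraries with spermatid transcripts 275 genes were shared in place of 340.

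**Figure D5:**
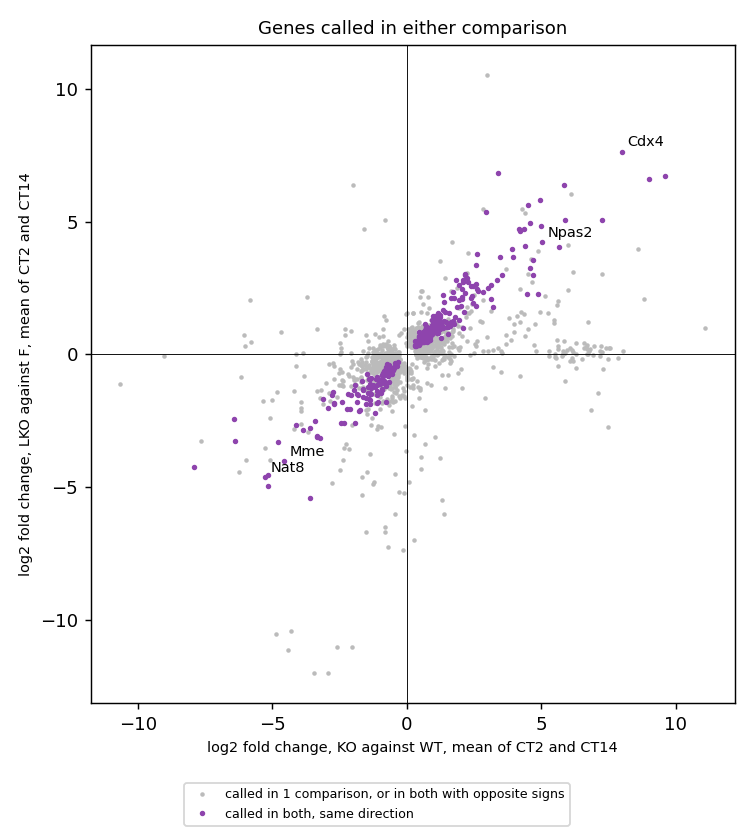
Log2 fold change of KO against WT (horizontal) and of LKO against F (vertical), each as the mean of CT2 and CT14, for the 1405 genes called in either comparison. The 340 genes called in both with the same direction are in purple, and Npas2, Nat8, Mme and Cdx4 are labelled.

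The difference of the KO and LKO effects was tested. The acyltransferase gene Acnat2 was higher in KO than WT and lower in LKO than F (difference 3.31 ± 0.45, adjusted p = 0.0063), with 151 ± 22 CPM in KO against 65.5 ± 5.7 in WT and 22.5 ± 6.6 CPM in LKO against 66.4 ± 16.7 in F at CT2 (SD, n = 3). Tmc5 differed by 8.94 ± 1.05, but F, with BMAL1 intact, lay 6.80 above WT. The matrix genes Ltbp4 (-1.68 ± 0.25) and Tnxb (-1.54 ± 0.25) were lower in KO relative to their LKO effect. Slc3a1 (1.83 ± 0.30), an amino acid transporter subunit gene, was lost only without LKO CT14 replicate 3 (adjusted p = 0.0538), and Lbp (1.94 ± 0.34), Crym (2.68 ± 0.53), Etnppl (-2.08 ± 0.40), Nrep (-1.79 ± 0.35) and Degs1l (-2.32 ± 0.45) were lost without any 1 of 10, 20, 19, 19 and 19 of the 24 libraries (adjusted p up to 0.0721, 0.130, 0.122, 0.109 and 0.122). Acute phase genes, with 1 of 21 higher over all genes and 19 adjusted over the list alone, had a median difference of 1.22 (adjusted p = 8.49e-23, adjusted p = 0.0896 with an estimated correlation). Acute phase and neutrophil sums were 59596 and 52.8 CPM in F CT2 replicate 3 and 39738 and 71.8 CPM in F CT14 replicate 2, against 18813 and 4.01 CPM in F CT14 replicate 1. In edgeR 22 genes were called (9 higher, 13 lower), and 223 by DESeq2 (133 higher, 90 lower). The count lay between 7 and 14 without any 1 of WT CT2 replicate 3, WT CT14 replicates 1 and 2, KO CT2 replicates 1 and 3, KO CT14 replicate 1, F CT2 replicate 1, F CT14 replicates 2 and 3 and LKO CT14 replicates 2 and 3. It was 44 without WT CT2 replicate 1 and 37 without F CT14 replicate 1.

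F was compared with WT to show how far the controls differed without any loss of BMAL1. The interferon-inducible gene Ifi202b was at 2.57 ± 0.93 CPM (SD, n = 6) in WT and at 0 in every F library, at least 88.6-fold lower. Pianp (-4.36 ± 0.69), the actin-bundling gene Pls1 (-3.72 ± 0.46), Fam171b (-3.48 ± 0.53) and the cytochrome gene Cyp2b10 (-3.65 ± 0.76) were also lower in F, the last uncalled without F CT2 replicate 3 (adjusted p = 0.0509). Tmc5 (6.80 ± 0.83), the imprinted gene Peg10 (3.11 ± 0.55), Iglv1 (2.82 ± 0.58) and the muscarinic receptor gene Chrm3 (3.11 ± 0.68) were higher, Chrm3 uncalled without WT CT14 replicate 1 or 2 (adjusted p = 0.0511 and 0.0566). Serpina1e (2.60 ± 0.58) was lost without any 1 of 6 libraries (adjusted p up to 0.0657). In edgeR 521 genes were called, 334 higher and 187 lower. Of the 334, 115 were among the 128 genes that followed the spermatid transcripts, which every F library and no WT library held. Line and spermatid transcripts can be told apart here only through the 2 KO libraries, and with these transcripts as a covariate 31 genes were called (5 higher, 26 lower). Pianp, Fam171b and Tmc5 remained called and Ifi202b, Pls1, Cyp2b10, Peg10, Chrm3, Iglv1 and Serpina1e did not (adjusted p of 0.134 to 0.483). Pancreatic acinar markers had 2 of 11 genes higher (11 adjusted over the list alone, adjusted p = 0.428 with an estimated correlation), and 152 genes were called without the 2 F libraries that held them (74 higher, 78 lower). With limma-trend 158 genes were higher and 145 lower, and with a filter of CPM 1 in 3 libraries 124 of 256 were lower. The split was 281 and 245 without F CT2 replicate 3 and LKO CT2 replicate 3. Camera called 16 lists, and 0 held with an estimated correlation. The count was 258, 312, 236, 311 and 314 without WT CT2 replicate 3, WT CT14 replicate 1, 2 or 3 or F CT14 replicate 3.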

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

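The tests that weigh explanations in this part were chosen after the result was seen, and the tests with other splits of the libraries were chosen before the data were examined.

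The difference between the time effects of KO and WT drew attention because the effect of time was itself tested for a difference between genotypes. In edgeR it called 164 genes. The genes taken by the naming rule were Ciart (-8.61), Dbp (-6.12) and Usp2 (-5.51) on the lower side and Npas2 (7.44), Dhrs9 (6.89) and Nckap5 (4.80) on the higher side, on the log2 scale. Of 100 splits of these libraries, 11 called as many genes, with up to 579 in a split other than the real one. In 11 of the other splits the genotypes fall unevenly on the times, so that the effect of genotype itself enters as a difference between times, and 6 of the 10 other splits as large are among these. A split that calls several times the real count thus points to the genotypes as a structure of the samples, and these splits do not settle whether chance can be excluded. For gene lists, 25 of 100 splits called as many as the 12 called with the real split, with up to 19.

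For the same difference between LKO and F, 23 genes were called. The naming rule took Dbp (-4.20), Per3 (-3.77) and Wee1 (-3.27) on the lower side and Npas2 (6.16), Loxl4 (4.92) and Cdkn1a (3.59) on the higher side. Of 100 splits 13 called as many genes, with up to 562, and 6 of the 12 others are among the 11 uneven ones, so these splits do not settle whether chance can be excluded either. For lists, 15 of 100 splits called as many as the real 13, with up to 18.

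The KO and LKO effects differed for 22 called genes. The rule took Degs1l (-2.32), Etnppl (-2.08), Nrep (-1.79), Ltbp4 (-1.68) and Tnxb (-1.54) as lower. Tmc5 (8.94, and 6.80 in F against WT), Acnat2 (3.31), Crym (2.68), Lbp (1.94) and Slc3a1 (1.83) were higher. Of 100 splits only the real one called as many genes (17 in the highest other), but it called 7 without LKO CT14 replicate 3. For lists 26 of 100 splits called as many as the real 12, with up to 15. Chance is excluded for neither.

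The 254 genes called for time in WT and in F had a median signed log2 time difference of 0.49 in LKO and -0.01 in KO. A larger time difference in F than in WT is argued against by medians of 1.27 and 1.36. Hepatocytes with an intact clock left in LKO may explain it and predict one part kept by all genes. E-box clock genes kept a median of 0.168 of the floxed time difference (quartiles 0.107 and 0.503). Other genes kept 0.420 (0.132 and 0.791), spreads too wide to test this. Bmal1 (6.57 to 7.91 CPM at CT2, 5.46 to 5.96 at CT14 in LKO) leaves such hepatocytes and other cells without Cre open. Time cues from outside the hepatocyte clock may explain it too and predict a larger part kept by the other genes. The difference in medians was 0.252 (two-sided permutation p = 0.113, 12 and 242 genes, not independent), leaving this open.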

How the results depend on the processing

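Counts divided by 4, leaving out F CT2 replicate 3 and LKO CT2 replicate 3, these and KO CT2 replicate 1, the 2 F libraries with pancreatic transcripts or the 2 KO libraries with spermatid transcripts, a covariate for spermatid transcripts, and leaving out each library in turn for gene lists, were tests chosen after the result was seen, and the other alternatives were planned. Among 711 values of named genes 0 were called in the opposite direction or lost their call with a change of sign. Outside these, Cpa1 in LKO against F (mean) lost its call and changed sign, from -10.56 to 0.09, without the 2 F libraries with pancreatic transcripts. The balance of calls turned too. F against WT went from 334 higher and 187 lower to 74 and 78 without the 2 F libraries with pancreatic transcripts and to 5 and 26 with the spermatid covariate. The time difference of KO and WT went from 103 and 61 to 67 and 76 with limma-trend, LKO against F at CT14 from 167 and 187 to 712 and 148, and KO effect against LKO effect from 9 and 13 to 133 and 90 with DESeq2. Of the 711 values, 704 stayed on their side of the threshold with RLE scaling, 704 with counts divided by 4, 657 with the replicate block, 639 without a count filter and 620 with limma-trend, 687 of 704 with DESeq2 and 700 of 708 with the CPM filter. With only the groups compared 527 of 708 did (174 weaker), and without each library in turn 5436 of 6558 (1113 weaker). Counts not given below stayed within 1.5 times. For counts that moved, the cause was not tested, except that leaving out libraries lowers the number of samples.

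With DESeq2, KO against WT had 1801 genes (mean), 394 (CT2) and 1752 (CT14), LKO against F 1066, 436 and 781, and F against WT 1071. Time had 979 genes in WT, 38 in KO, 1187 in F and 691 in LKO. The differences had 412 (time, KO and WT), 139 (time, LKO and F) and 223 (KO effect and LKO effect), and the overlap of KO and LKO calls was 555. With limma-trend on TPM, KO against WT had 1690 genes (mean) and 196 (CT2), LKO against F 1645, 219 and 860, F against WT 303 and time in KO 1. With only the groups compared, KO against WT at CT2 had 65, LKO against F 1 at CT2 and 896 at CT14, time 33 in F and 46 in LKO, the time difference of LKO and F 11 and F against WT 343. Without a count filter, time in LKO had 87 and KO effect against LKO effect 14. With a filter of CPM 1 in 3 libraries, F against WT had 256. With counts divided by 4, LKO against F at CT2 had 125. With replicate number as a block (paired), time in LKO had 81, and the replicate numbers matched the best correlated library in 8 of 24 cases. The overlap with at least 2-fold changes was 165. Of 162 list calls, 20 held with an estimated correlation and 62 with fry. Of these 20, 10 still held without each library in turn.

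Without F CT2 replicate 3 and LKO CT2 replicate 3, KO against WT had 1666 (mean), 186 (CT2) and 1728 (CT14), LKO against F at CT14 669, time in WT 944, and the time differences 311 (KO) and 75 (LKO). Without KO CT2 replicate 1 as well, KO against WT at CT14 had 1915, LKO against F at CT14 754, time 1100 in WT and 288 in LKO, and the time differences 251 and 85. Without the 2 F libraries with pancreatic transcripts, time in F had 207 and F against WT 152. Without the 2 KO libraries with spermatid transcripts, time in KO had 4 and the time difference of KO and WT 85. With spermatid transcripts as a covariate, F against WT had 31.

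Without each library in turn, the counts ran from 763 to 987 (KO against WT, mean), 50 to 108 (CT2) and 632 to 902 (CT14), 415 to 694 (LKO against F, mean), 44 to 155 (CT2) and 171 to 276 (CT14). Time gave 270 to 414 in WT, 0 to 8 in KO, 240 to 578 in F and 10 to 59 in LKO. The differences gave 101 to 158 (time, KO and WT), 12 to 57 (time, LKO and F) and 7 to 44 (KO effect and LKO effect), and F against WT 236 to 477. Estimated counts limit the precision for weakly expressed genes, and fold changes against groups at 0 are bounds set by a floor of 3 counts.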

Other observations

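The tests that weigh explanations in this part, the gene windows around Bmal1 and the list of spermatid genes were chosen after the result was seen, and the splits of the libraries were chosen before the data were examined.

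The summed level of the 9 hepatocyte markers was 116253 CPM in WT at CT2 and 113461 CPM at CT14, and 84754 and 88999.5 CPM in KO. It was 118135 and 120830 CPM in F and 85575 and 80327 CPM in LKO. Alb, the gene of the main plasma protein, stood at CT2 at 76771 ± 15655 CPM (SD, n = 3) in WT, 40592 ± 13640 CPM in KO, 75090 ± 1498 CPM in F and 41696 ± 6605 CPM in LKO. As the mean of both times the log2 fold change of Alb was -0.87 ± 0.17 in KO (adjusted p = 0.00269) and -0.97 ± 0.17 in LKO (adjusted p = 0.0016), while the list as a whole was called neither in KO (adjusted p = 0.362) nor in LKO (adjusted p = 0.971).

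The summed level of heat shock genes, whose products fold other proteins, went from 2654 CPM at CT2 to 6013 CPM at CT14 in WT and from 2919 to 5372 CPM in F. The time effect on the list held with an estimated correlation in WT (adjusted p = 0.0447, lost without any 1 of 5 of the 6 libraries) and not in F (adjusted p = 0.267). The level went from 3496 to 3292 CPM in KO and from 2613 to 4031 CPM in LKO. The difference between the time effects of KO and WT had 0 of 18 genes called over all genes and 9 lower when adjusted over the list alone, with an adjusted p = 0.0893 with an estimated correlation.

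Spermatid transcripts were present at low levels in 14 libraries. Prm2 averaged 1.91 CPM in these and 0.0024 CPM in the other 10. Of the 128 genes that followed this division, 21 were on the list, and 0 genes were lower in each of the 14 libraries than in each of the 10. Besides KO against WT and F against WT, 0 calls of any other comparison were among the 128 genes.

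Of the 100 tested genes nearest to Bmal1, 50 on each side in the order of build GRCm38, 10 were called in KO against WT, among them Tmc5, Lyve1, Dennd2b and Galnt18. An interval of 10 Mb on each side was looked at first (15 of 194 genes, 7.73% against 5.40% of all) and then 50 and 100 genes on each side, and 100 on each side held 15 calls against a 95th percentile of 18. DNA of the targeted allele's strain around the locus may account for some of the 10. The window holds no excess of calls, since 10 equals the 95th percentile of windows of that size and 7.75% of windows hold as many, but 4 of the 10 (Tmc5, Acsm5, Tmc7 and Cyp2r1) were also called in the same direction in F against WT, compared with 129 of 1096 called genes elsewhere (11.8%, Fisher's exact test, p = 0.0235), and F against WT had 7 calls in the window against a 95th percentile of 6. A response to loss of BMAL1 stays open too: 0 of the 10 were called in the same direction in LKO, against 339 of 1096 elsewhere (30.9%, Fisher's exact test, p = 0.037), but 7 of the 10 had the same sign there (87.1% elsewhere), and time in WT also had 7 calls in the window against a 95th percentile of 6.

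Pancreatic enzymes were lower in LKO than in F for 5 of 11 markers. Pancreatic tissue in 2 floxed libraries may account for it, since 0 of the markers were called without F CT2 replicate 3 and F CT14 replicate 3, and the levels of the 11 markers in these libraries correlated with r = 0.727 across genes. The most abundant markers, Ctrb1 and Cela2a, stood at 613 and 396 CPM in the first and 147 and 98.2 CPM in the second, and the list summed to at most 6.63 CPM in the other F libraries. Lower expression in liver cells without BMAL1 is argued against as the cause of these calls, since without the 2 libraries the log2 fold change of all 5 called markers was smaller by more than 2 of its standard errors (Ctrb1 from -10.43 ± 2.55 to -1.49 ± 1.65, Cela2a from -6.03 ± 1.48 to -0.02 ± 0.51). A small difference was not resolved, as 4 of the 5 had a lower median in LKO than in the other 4 F libraries and 0 were separated.

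Other splits of the libraries gave these counts. For KO against WT as the mean of both times, 1 of 100 splits, the real one, called as many as 1107 genes (547 in the highest other) and 4 as many as 16 lists (up to 18). For LKO against F these were 2 for 642 genes (up to 712) and 2 for 17 lists (up to 18), and for F against WT 1 for 521 genes (up to 16) and 3 for 16 lists (up to 18). The KO and LKO overlap of 340 genes was 0 in other splits, but a median of 0 calls left them little to share. Chance is excluded for the gene counts of KO and F against WT. It is not for the overlap, for LKO (another split called more) or for lists (up to 18 called).

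With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. For KO against WT at CT2 the real split called 106 genes and the highest other 5 (10 and 12 lists), and at CT14 1089 and 1 (13 and 12 lists). For LKO against F at CT14 they called 354 and 1 (16 and 14 lists). For CT14 against CT2 they called 521 and 2 genes in WT (6 and 14 lists), 0 and 6 in KO (3 and 10 lists), 545 and 30 in F (10 and 14 lists) and 174 and 0 in LKO (9 and 8 lists). For LKO against F at CT2 the real split called 82 genes and 9 lists and the highest others 1625 and 13. The split with 1625 genes set F CT2 replicates 1 and 3 and LKO CT2 replicate 3 against the rest, which points to a structure of these samples that does not follow genotype.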
